A study of Mus musculus with 6 samples.

How the data were processed

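H3K27ac CUT&RUN was performed on cells sorted from pooled mouse lungs at E16.5 with a commercial assay kit, and libraries were sequenced as paired-end reads on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt 4.8, Bowtie2 2.5.3, MACS2 2.2.9.1, deepTools 3.5.5, DiffBind 3.6.5, edgeR, HOMER and bedtools 2.31.1 and the genome build mm10, without the role or order of each. The use of the IgG libraries as the peak caller's control, and the peak caller's threshold, are not given in the sources used here.

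Each of the 4 analysed libraries had 1 deposited list of broad peaks, called per library and not on pooled samples, as the peak names show. The deposited score of a peak is the whole part of 10 times its −log10 q and was not used. The deposited ratio is the fold enrichment of the peak over the peak caller's background. The deposited −log10 p and −log10 q were used to rank and filter peaks within a list. The lowest deposited −log10 q was between 1.00 and 1.03 in the 4 libraries. A list holds only intervals above the peak caller's minimum, so the absence of a peak is not the absence of acetylation, and how much was called depends on depth, which the lists do not give. Broad peaks of this kind hold no counts per region over all libraries, so no count model was run, and DiffBind and edgeR, which need reads, were not rerun.

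Peaks on chromosomes 1 to 19, X and Y were kept, which left out 1 to 8 peaks per library. Gene positions came from a RefSeq table of the assembly GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on these chromosomes. All 391 symbols of the 28 gene lists, fixed before the data were examined, matched it. That table gives neither strand nor transcripts, and no genome sequence was used here. The planned use of transcription start sites was therefore replaced by gene ends, and the search for 24 motifs in distal regions and the alternative with the gene's 5′ end alone were not run. A gene domain was the gene body plus the intergenic bases nearer to it than to any other coding gene, up to 50 kb. A gene-end peak lay within 1 kb of either end of a gene, and a distal region more than 2 kb from either end of any annotated gene, so start sites inside genes count as distal. Of the coding genes, 17.5% overlap another coding gene.

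Regions were compared by overlap of at least 1 bp after merging overlapping peaks of the 4 libraries. The covered length per domain was tested with limma 3.58.1 (R 4.3.3) on log2(kb + 0.5), median-centred over the 6918 domains with a peak in all 4 libraries, with an intensity trend and Benjamini-Hochberg adjustment, for the 10486 domains with a mean of at least 0.5 kb. The median difference over all tested domains was 0.03. Gene lists with at least 2 tested members were compared with all other tested domains by camera (limma) with a preset correlation of 0.01 and, as an alternative, an estimated correlation. Lists at gene ends and distal shares were tested by two-sided Fisher's exact tests. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

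The coverage computation was tested on simulated intervals. The limma step was tested on 20 simulated sets of 10486 domains with 200 changed domains: it recovered 1.7%, 23.5%, 67.1% and 91.7% of changes of 1, 2, 3 and 4 on the log2 scale, with 5.03% false calls. Differences of up to 4-fold were thus mostly missed in simulated comparisons of 2 libraries against 2. The simulated noise was normal with the spread fitted to each domain, as limma assumes. Real lengths include domains without a peak in some libraries, so these rates need not hold for the data.

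Genes were named by a rule fixed before the data were examined: the sort markers and Myrf; the 10 largest differences in each direction among called domains whose libraries did not overlap; up to 4 members with the smallest adjusted p per list and direction, with members needed to say that a list did not pass; the 3 widest regions of each class; and up to 10 list members per class at gene ends. A few genes that this rule names are not reported here. Groups came from the sample titles. The alternatives covered the peak threshold, the number of peaks, the overlap and merging rules, the domain definition, the scaling, the pseudocount, the filter, the replicate numbers as a block and leaving out each library. Thresholds of −log10 q of at least 2 and a peak width of at least 1 kb were chosen after seeing the data. The titles' cell numbers, from 25k to 200k, differ between libraries. Mesothelium replicate 2 and epithelium replicate 1 share 100k cells, and with 1 library of each no test at equal cell number was made.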

Results

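Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by CUT&RUN, in which an antibody directs a nuclease to cut out the DNA around a chromatin mark, in cells sorted from mouse lungs at E16.5, an age in days of embryonic development. The series belongs to a study of MYRF, a membrane-bound transcription factor, in the mesothelium, the cell layer that covers the lung. Mesothelial cells were sorted as positive for podoplanin (PDPN) and negative for EPCAM, CD45, CD31 and the dead-cell dye DAPI. Epithelial cells were sorted as positive for both PDPN and EPCAM and negative for the other 3. The peak lists of 2 mesothelium and 2 epithelium H3K27ac libraries were analysed. Another 2 libraries, made with a non-specific IgG antibody from epithelial cells, were not analysed here, so no background level stands beside the peaks. According to the sample titles, mesothelium replicates 1 and 2 came from 25k and 100k cells and epithelium replicates 1 and 2 from 100k and 200k cells, although the protocol names a narrower range of cell numbers for this mark. The embryos came from matings of mice with floxed Myrf alleles, for which the labels name no Cre recombinase, and the series text calls the cells wildtype. They were treated as unmodified here, which the peak lists do not test. Lungs were pooled before sorting, and nothing in the labels says that replicates came from separate pools, so p-values measure only the spread between these libraries, which may be technical.

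The mesothelium lists held 39010 and 41532 peaks that covered 35.7 and 39.8 Mb, and the epithelium lists held 47873 and 46633 peaks that covered 44.4 and 41.4 Mb. Median peak widths were 588 and 613 bp in mesothelium and 580 and 571 bp in epithelium. The deposited fold enrichment of a peak over the peak caller's background had medians between 3.47 and 3.75 in the 4 libraries. The median −log10 q was 1.72 and 2.05 in mesothelium and 1.56 and 1.56 in epithelium, near the lowest listed value of 1.00. A −log10 q of at least 4 was reached by 623 and 2267 peaks in mesothelium and by 569 and 576 in epithelium. Read depth is unknown, since the lists hold no counts.

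The 2 libraries of a cell type shared more acetylated sequence with each other than with the libraries of the other cell type. The Jaccard index, the bases covered in both libraries divided by the bases covered in either, was 0.132 for the mesothelium pair and 0.140 for the epithelium pair. It lay between 0.0912 and 0.102 for the 4 pairs of different cell types. All overlaps were low, and 26.8% of the peaks of mesothelium replicate 1 overlapped a peak of replicate 2. With 2 libraries against 2 there are 3 ways to split the libraries, so the smallest exact p-value is 0.333 and no test was made. Among peaks with a −log10 q of at least 4 this separation was lost: the lowest index within a cell type minus the highest between cell types was −0.00222, against 0.0303 for all peaks.

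Regions acetylated in 1 cell type only outnumbered those that mixed libraries of both cell types gave. Overlapping peaks of the 4 libraries were merged into 132165 regions, of which 80.7% were present in 1 library. There were 3445 mesothelium-only regions, present in both mesothelium libraries and neither epithelium library, 4384 epithelium-only regions and 4281 regions present in all 4 libraries. The error of these counts was read from regions present in exactly 1 mesothelium and 1 epithelium library. Those 4 crossed patterns held 1509 to 2000 regions, with a mean of 1767.5 ± 205.2 (SD, n = 4 patterns). Mesothelium-only regions were thus 1.95 times and epithelium-only regions 2.48 times as frequent as the crossed mean. The epithelium lists held more peaks, and with equal numbers of peaks per library there were 3574 mesothelium-only and 3568 epithelium-only regions. With peaks of a −log10 q of at least 4, 85 mesothelium-only and 10 epithelium-only regions were left. A region needs a peak in only 1 library of a cell type when the other is left out, and there were then 28906 mesothelium-only regions without mesothelium replicate 1 and 26549 without replicate 2, and 33918 epithelium-only regions without epithelium replicate 1 and 35074 without replicate 2.

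**Figure D1:**
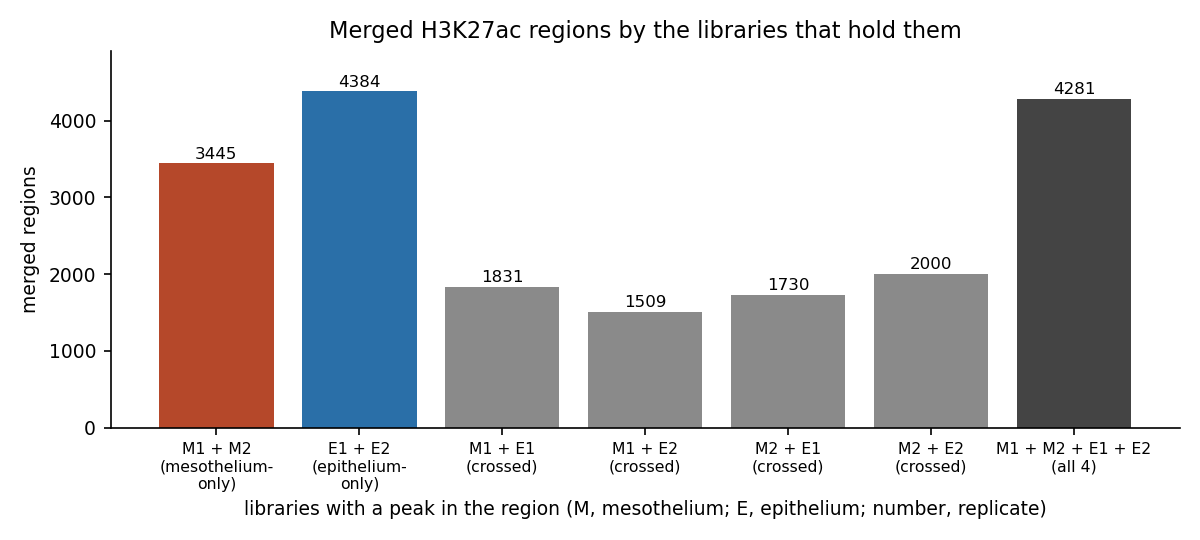
Number of merged H3K27ac regions (vertical axis) by the libraries in which a peak overlaps the region (horizontal axis; M, mesothelium; E, epithelium; the number is the replicate). The 3445 mesothelium-only and 4384 epithelium-only regions exceed each of the 4 crossed patterns, which hold 1509 to 2000 regions.

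The widest mesothelium-only region spanned 15.8 kb of chromosome 11 (19005715 to 19021472, mm10) and overlapped 1 end of Meis1, which encodes a homeodomain partner of HOX proteins. The second lay within Bnc2, a basonuclin zinc-finger gene (chromosome 4, 84355283 to 84363762, 8.48 kb), although mesothelium replicate 1 covered only 0.976 kb of it. The third lay within Ninl (chromosome 2, 150996686 to 151005012, 8.33 kb). The widest epithelium-only region spanned 10.4 kb within Zfp608, a zinc-finger gene (chromosome 18, 54913368 to 54923790), although epithelium replicate 2 covered only 2.27 kb of it. The next was intergenic with respect to coding genes, 22.2 kb from Wdr11 (chromosome 7, 129657897 to 129666991). The third lay within Atp8a1 (chromosome 5, 67836384 to 67845190, 8.81 kb).

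Cell-type-only regions lay away from gene ends more often than regions shared by all libraries. A region counted as distal when it was more than 2 kb from either end of any annotated gene. By this measure 73.6% of mesothelium-only regions (2534 of 3445) and 79.1% of epithelium-only regions (3469 of 4384) were distal, against 44.0% of regions present in all 4 libraries (1883 of 4281). The odds ratios were 3.54 (p = 1.1e-153) and 4.83 (p = 6.1e-255) by two-sided Fisher's exact tests, which treat regions as independent. The mesothelium ratio was 5.71 without mesothelium replicate 1 and the epithelium ratio 2.43 without mesothelium replicate 2, and neither passed with a −log10 q of at least 4 (p = 1.0 and 0.304, Fisher's exact tests). Regions in the crossed patterns were distal in 73.7% of cases, so mesothelium-only regions did not differ from them (odds ratio 0.992, p = 0.869, Fisher's exact test), while epithelium-only regions did (odds ratio 1.35, p = 3.5e-11). Shared regions were also wider, with a median of 3130 bp against 1516 and 1586 bp, which by itself brings a region nearer to a gene end.

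Peaks at gene ends found in epithelium only included those of several lung epithelial regulators, and peaks found in mesothelium only included those of anterior Hox genes. Of 21887 protein-coding genes, 657 had a peak within 1 kb of either gene end in both mesothelium libraries and neither epithelium library, and 441 had the opposite pattern. The crossed patterns held 173 to 562 genes, so the epithelium-only count lay within their range. Mesothelium replicate 2 had peaks at the ends of 7449 genes, against 5873, 6070 and 6092 genes in the other 3 libraries. Of 20 lung epithelial transcription factor genes, 7 had epithelium-only peaks (35.0% against 1.99% of other genes, adjusted p = 4.4e-06, Fisher's exact test with Benjamini-Hochberg adjustment over 56 tests). These included Nkx2-1, which specifies lung epithelium, Grhl2, Etv5, Klf5, Irx1 and Irx2. Epithelium-only peaks were also found at 4 of 17 FGF pathway genes (Fgf1, Fgfr2, Spry1 and Etv5, adjusted p = 0.0059, Fisher's exact test) and at 4 of 20 junction and keratin genes (Cdh1, Cldn7, Marveld2 and Spint1, adjusted p = 0.0085, Fisher's exact test). In mesothelium, 6 of 15 anterior Hox genes, which encode positional homeodomain factors, had mesothelium-only peaks (among them Hoxa5, Hoxb2, Hoxb3, Hoxb4 and Hoxb5, adjusted p = 8.0e-05, Fisher's exact test). Of 20 mesothelial markers, Wt1, Lrrn4 and Muc16 had mesothelium-only peaks, which did not pass the adjustment (adjusted p = 0.218, Fisher's exact test). When 1 library is left out, fewer libraries must have or lack a peak, and the counts rose to between 1308 and 1826 genes for mesothelium and between 741 and 1242 for epithelium. The 1 mesothelium list and 3 epithelium lists called here became 0 and 1 with a −log10 q of at least 2 and 0 and 0 with at least 4. They became 3 and 5 without mesothelium replicate 1, and the epithelium lists 2 without mesothelium replicate 2 or epithelium replicate 1, 4 without epithelium replicate 2 and 2 with equal numbers of peaks.

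Acetylated length per gene domain, the kilobases under peaks within a gene and the intergenic bases nearest to it up to 50 kb away, differed between mesothelium and epithelium at 413 of 10486 tested domains. Of these, 148 were longer in mesothelium and 265 were longer in epithelium (limma, Benjamini-Hochberg adjusted p under 0.05), and 1862 domains had an unadjusted p under 0.05. The lengths of the 2 cell types did not overlap at 48.1% of the tested domains, against 33.3% by chance. Fold differences below are on the log2(kb + 0.5) scale after median centring, which understates differences of short domains. The calls changed with this scale, with the scaling of the libraries and with the peaks admitted. Scaled to total covered length, 88 domains were longer in mesothelium and 122 in epithelium, and after quantile normalization 94 and 125. With 0.1 kb added in place of 0.5 kb, Meis1 alone was called (1654 domains at unadjusted p under 0.05), and no domain was called from peaks with a −log10 q of at least 2 (960 domains) or from peaks of at least 1 kb (1653 domains). The number longer in epithelium was 471 without mesothelium replicate 1, 117 without epithelium replicate 1 and 80 without epithelium replicate 2.

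In mesothelium, the 10 domains with the largest differences included those of the homeobox genes Meis1, Hoxb3 and Hoxa3, the T-box gene Tbx5 and the collagen gene Col3a1. Meis1 (chromosome 11, 18880428 to 19019651, mm10) carried 43.4 and 48.8 kb of acetylated sequence in the mesothelium libraries and 1.68 and 2.08 kb in the epithelium libraries (log2 difference 4.36, SE 0.42, adjusted p = 3.8e-06, limma). Hoxb3 (chromosome 11, 96307101 to 96347930) carried 19.2 and 18.9 kb against 0.480 and 0.488 kb (log2 difference 4.38, SE 0.56, adjusted p = 0.00020), and Hoxa3 (chromosome 6, 52169059 to 52213067) carried 11.2 and 17.7 kb against 0.384 kb and no peak (log2 difference 4.52). As annotated, Hoxa3 overlaps Hoxa4, Hoxa5 and Hoxa6, and Hoxb3 overlaps Hoxb4, so their peaks cannot be assigned to 1 gene. Tbx5, a T-box factor of lung and heart mesoderm, carried 8.37 and 12.7 kb against no peak and 0.324 kb (log2 difference 4.13, adjusted p = 0.0011). Med13l, on the same chromosome, carried 8.67 and 18.7 kb against 0.857 kb and no peak. Col3a1, a fibrillar collagen gene, carried 9.05 and 12.3 kb and had no peak in either epithelium library (adjusted p = 0.00058). Gpm6a, a membrane glycoprotein gene listed as a mesothelial marker, carried 9.84 ± 4.49 kb (SD, n = 2), and Fnbp1 carried 9.42 ± 2.70 kb, again without a peak in epithelium. Gypc and Lrrc69 completed the 10 largest differences. Each of these 10 differences kept its direction when any 1 library was left out. Such a fit takes its spread from the cell type that keeps both libraries, so it is not a stricter test. Col3a1 lost its call with gene bodies and 5 kb flanks as domains (limma adjusted p = 0.077, and 3.4e-07 to 0.173 over all alternatives).

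In epithelium, the 10 largest differences included Nkx2-1 and Foxa2, which encode regulators of lung endoderm, the morphogen gene Shh and the tight-junction gene Cldn18. Nkx2-1 (chromosome 12, 56531935 to 56536908, mm10) carried 28.1 and 33.7 kb in the epithelium libraries and 2.95 kb and no peak in the mesothelium libraries (log2 difference −4.51, SE 0.67, adjusted p = 0.00058, limma). Foxa2 (chromosome 2, 148042877 to 148046969), a forkhead factor of endoderm, carried 36.3 and 45.5 kb against 5.85 and 0.417 kb (log2 difference −4.03, adjusted p = 0.00074). The zinc-finger gene Prdm16 carried 39.5 and 41.9 kb against 3.74 and 0.349 kb (log2 difference −4.38, adjusted p = 0.00021). The homeobox genes Irx5 and Irx2 carried 12.5 and 22.6 kb and 14.9 and 11.1 kb, against at most 0.886 kb in mesothelium. Etv5, an ETS factor downstream of FGF signalling, carried 15.4 and 14.9 kb against 0.885 kb and no peak. Cldn18, a claudin of alveolar tight junctions, carried 22.5 and 14.0 kb against 0.378 and 0.531 kb. Shh, which encodes Sonic hedgehog, carried 8.90 and 7.63 kb and had no peak in either mesothelium library (adjusted p = 0.0015). Epb41l1 and Pdpn completed the 10 largest differences, all of which kept their direction when any 1 library was left out. With gene bodies and 5 kb flanks as domains, Shh lost its call (adjusted p = 0.051; 1.8e-05 to 0.192 over all alternatives).

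**Figure D2:**
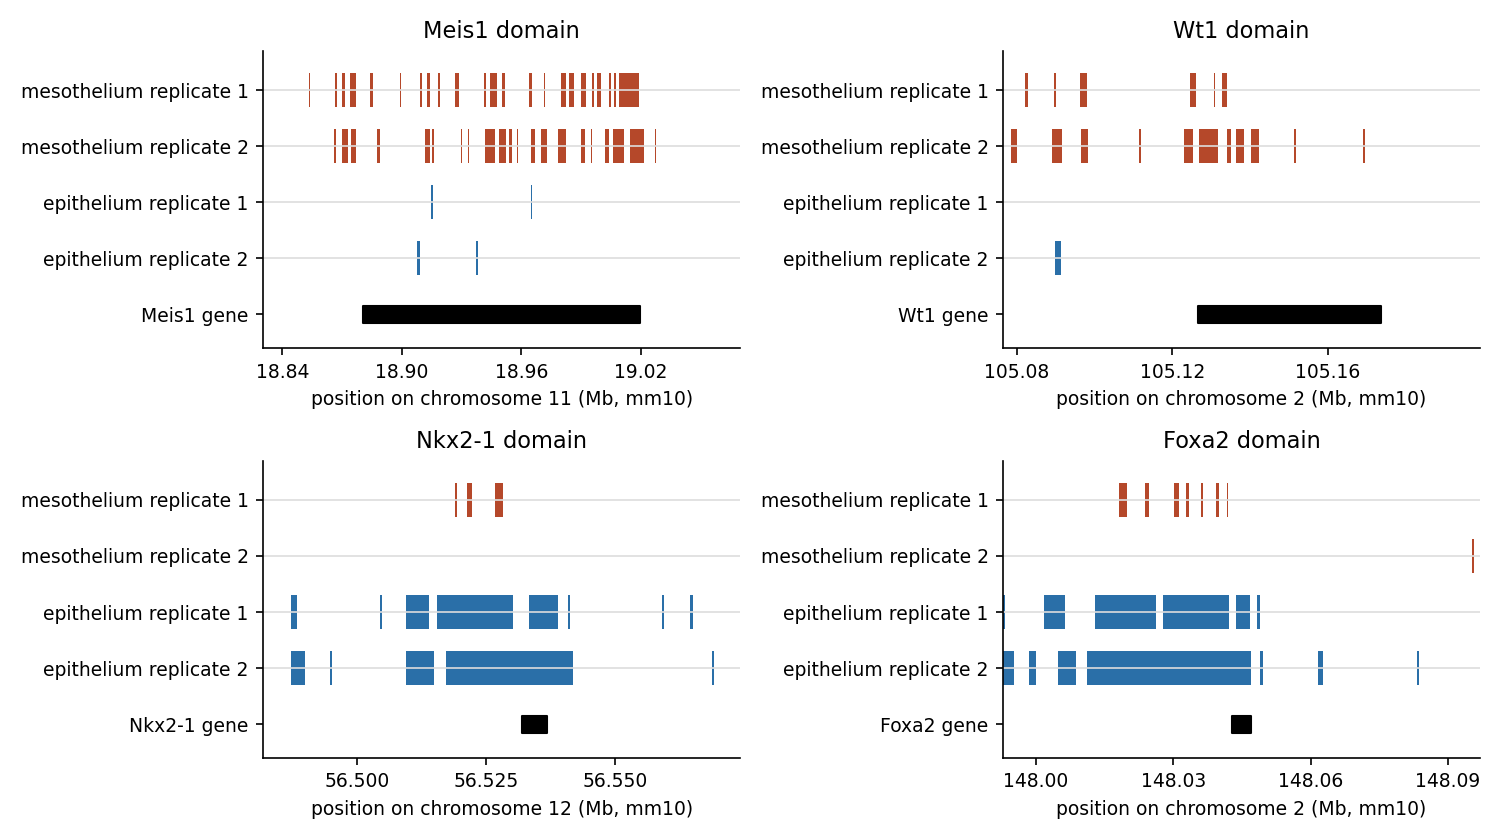
H3K27ac peaks of the 4 libraries (rows, filled boxes) across the domains of Meis1, Wt1, Nkx2-1 and Foxa2 by position in Mb (horizontal axes, mm10), with the annotated gene as a black bar. Meis1 held 43.4 and 48.8 kb of peaks in mesothelium against 1.68 and 2.08 kb in epithelium, and Foxa2 held 36.3 and 45.5 kb in epithelium against 5.85 and 0.417 kb in mesothelium.

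Of the genes that defined the sorts, Pdpn, the positive marker of both gates, carried 10.4 and 8.97 kb in epithelium against 0.364 kb and no peak in mesothelium (log2 difference −3.89, SE 0.67, adjusted p = 0.0016, limma). Epcam carried 5.35 and 4.48 kb in epithelium and 0.685 and 1.02 kb in mesothelium, which did not pass (log2 difference −1.94, SE 0.65, adjusted p = 0.103). Epcam was called in 1 of 17 alternatives (limma adjusted p = 0.041). Pecam1, which encodes CD31, carried 3.48 ± 2.76 kb in mesothelium and 2.11 ± 0.272 kb in epithelium (SD; adjusted p = 0.780, limma). Ptprc, which encodes CD45, had 0.979 kb in epithelium replicate 2, no peak elsewhere and no test. Of the 3 tested sort markers, Pdpn was called (2 were adjusted over the list alone, both longer in epithelium), with a list test at the threshold (camera adjusted p = 0.042, adjusted p = 0.447 with an estimated correlation, 0.197 without mesothelium replicate 2, 0.069 without epithelium replicate 1 and 0.051 without epithelium replicate 2; 0.016 to 0.447 over all alternatives). Myrf (chromosome 19, 10208271 to 10240777) had no peak in mesothelium replicate 1, 1.53 kb in replicate 2 and 1.49 and 1.23 kb in epithelium, and did not differ beyond the spread (log2 difference −0.82, SE 0.83, adjusted p = 0.653). Its interaction partner Tmem98 carried 3.83 and 3.46 kb in mesothelium and 1.87 and 1.56 kb in epithelium (log2 difference 0.96, adjusted p = 0.449), and its paralogue Myrfl was not called either (adjusted p = 0.303; the 3 genes as a list, camera adjusted p = 0.549).

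Mesothelial markers such as Wt1 and Gpm6a had longer acetylated domains in mesothelium, and among mesothelial transcription factors the difference lay with a minority of the genes. Of 16 tested mesothelial markers, 6 were longer in mesothelium (8 adjusted over the list alone) and none in epithelium, with a median log2 difference of 2.00 (camera adjusted p = 1.1e-05, adjusted p = 0.447 with an estimated correlation). Wt1, a zinc-finger factor of mesothelium, carried 6.42 and 19.4 kb against no peak and 1.47 kb (log2 difference 3.62, SE 0.72, adjusted p = 0.0055, limma). Bnc1 carried 4.28 and 4.69 kb and had no peak in epithelium (adjusted p = 0.011, 0.094 without mesothelium replicate 2; 0.0017 to 0.636 over all alternatives). Mesothelin, Msln, was not longer in mesothelium, with 0.544 and 0.893 kb against 1.19 and 4.29 kb (log2 difference −1.17, adjusted p = 0.438). Of 13 tested mesothelial transcription factors, 5 were longer in mesothelium, with the same count adjusted over the list alone and a median log2 difference of 0.32 against a mean of 1.36 (camera adjusted p = 0.0057, adjusted p = 0.499 with an estimated correlation). They were Meis1, Gata5, Meis2, Wt1 and Bnc1, and Gata5, a zinc-finger factor, carried 7.44 and 8.37 kb against 0.647 kb and no peak (not called with 5 kb flanks, adjusted p = 0.176; 0.00010 to 0.176 over all alternatives), while Meis2 lost its call without mesothelium replicate 2 (adjusted p = 0.105; 0.00022 to 0.234 over all alternatives). The other 8 did not pass, and this list was not called without mesothelium replicate 2 (adjusted p = 0.096; 7.4e-05 to 0.861 over all alternatives). All 7 tested anterior Hox genes had a positive difference, 2 of them called (5 adjusted over the list alone), with a median of 2.11 (camera adjusted p = 1.2e-06, adjusted p = 0.412 with an estimated correlation). No peak was assigned to any of 24 posterior Hox genes in any library, although Hoxa6, inside Hoxa3 as annotated, had gene-end peaks in both mesothelium libraries.

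Epithelial genes had longer domains in epithelium as a group. Of 17 tested lung epithelial transcription factors, 11 were longer in epithelium (14 adjusted over the list alone), none was longer in mesothelium, and the median log2 difference was −2.61 (camera adjusted p = 7.6e-11, adjusted p = 0.447 with an estimated correlation). Of 16 junction and keratin genes, Cldn18, Spint2, Cdh1 and Cldn3 were longer in epithelium (10 adjusted over the list alone), and all 16 differences were negative (camera adjusted p = 2.4e-08, adjusted p = 0.412 with an estimated correlation). Cldn18 kept its call in each leave-out, whereas without epithelium replicate 2 the adjusted p was 0.054 for Spint2, 0.076 for Cdh1 and 0.128 for Cldn3, Spint2 and Cldn3 also lost their calls without epithelium replicate 1 (0.057 and 0.099) and Cldn3 without mesothelium replicate 2 (0.110). Their ranges over all alternatives were 3.6e-05 to 0.384, 1.0e-08 to 0.282 and 0.00086 to 0.618. Alveolar type 2 markers (3 of 10 longer in epithelium, 8 adjusted over the list alone, camera adjusted p = 4.2e-07) and alveolar type 1 markers (3 of 12, 4 adjusted over the list alone, camera adjusted p = 0.00016) followed, each with adjusted p = 0.447 with an estimated correlation. The type 2 calls were Sftpb, Sftpd and Etv5, which is also in the lists of lung epithelial transcription factors and FGF genes. Sftpb and Sftpd were called in 9 and 8 of 17 alternatives. Among the type 1 calls, Cldn18 is also in the junction and keratin list. Lmo7, a type 1 marker, carried 31.7 and 24.1 kb against 8.85 and 2.40 kb (adjusted p = 0.0066, 0.051 scaled to total covered length; 1.8e-08 to 0.189 over all alternatives), whereas Cav1, a caveolin listed with it, was longer in mesothelium (6.42 and 9.70 kb against 1.96 and 0.367 kb, adjusted p = 0.024), a call lost without mesothelium replicate 2 (adjusted p = 0.083) and without epithelium replicate 2 (adjusted p = 0.184; 0.0032 to 0.184 over all alternatives). None of 4 tested airway markers was called, also adjusted over the list alone, with a list test at the threshold (camera adjusted p = 0.042, adjusted p = 0.447 with an estimated correlation, 0.197 without mesothelium replicate 2 and 0.071 without epithelium replicate 2; 0.013 to 0.462 over all alternatives). Mesothelium replicate 1 held more acetylated sequence than replicate 2 at these genes, with 63.1 against 33.5 kb over the lung epithelial transcription factors and 18.0 against 11.6 kb over the junction and keratin genes, where the epithelium libraries held 247.0 and 258.0 kb and 92.6 and 96.6 kb.

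Genes of the Hedgehog and FGF pathways were called in both directions. In the Hedgehog pathway, Shh was longer in epithelium, and the transcription factor gene Gli2 (9.89 and 16.8 kb against 0.568 and 0.393 kb, log2 difference 3.84, adjusted p = 0.00092, limma) and the co-receptor gene Boc were longer in mesothelium. Boc lost its call without mesothelium replicate 2 (adjusted p = 0.123), epithelium replicate 1 (0.054) or epithelium replicate 2 (0.088; 0.0044 to 0.386 over all alternatives). In the FGF pathway, Etv5, Fgfr2, Spry1 and Fgf1 were longer in epithelium, and Fgf9 and Fgf2 in mesothelium. As annotated, Fgf1 overlaps Arhgap26 and Gm5820, and Fgf2 overlaps Nudt6, so their peaks cannot be assigned to 1 gene. Without epithelium replicate 2, Spry1 and Fgf1 lost their calls (adjusted p = 0.132 and 0.272; 0.00024 to 0.313 and 0.0027 to 0.321 over all alternatives), and Fgf2 lost its call without mesothelium replicate 1 (0.056), mesothelium replicate 2 (0.222) or epithelium replicate 1 (0.280; 0.014 to 0.317 over all alternatives). Fgfr2 carried 34.3 and 35.3 kb in epithelium against 5.76 and 7.75 kb (log2 difference −2.24, adjusted p = 0.00092). Fgf9, an FGF ligand gene, carried 2.38 and 12.9 kb in mesothelium against 0.369 and 0.302 kb (adjusted p = 0.027), a call lost without mesothelium replicate 2 (adjusted p = 0.409) and without epithelium replicate 2 (adjusted p = 0.061; 0.0015 to 0.5 over all alternatives). Wnt7b, a WNT ligand gene, carried 14.5 ± 1.36 kb in epithelium against 1.15 ± 0.491 kb (SD, n = 2; limma adjusted p = 0.0018, 0.062 with a domain reach of 100 kb; 2.4e-06 to 0.177 over all alternatives) and was the 1 call among 16 WNT genes. Aldh1a2, which encodes a retinoic acid synthesis enzyme, was the 1 call among 10 retinoic acid genes, with 3.46 and 9.01 kb in mesothelium against 0.848 and 0.290 kb (adjusted p = 0.032, 0.256 without mesothelium replicate 2 and 0.141 without epithelium replicate 2; 0.0058 to 0.569 over all alternatives). Tgfbr3 was longer in mesothelium and Tgfbr2 and Notch1 in epithelium, and each lost its call without epithelium replicate 1 (adjusted p = 0.206, 0.074 and 0.102) or without epithelium replicate 2 (adjusted p = 0.097, 0.207 and 0.251; 0.015 to 0.758, 0.00046 to 0.329 and 0.0045 to 0.337 over all alternatives). Lama3, a laminin chain gene, was the 1 call among 20 basement membrane genes, with 27.2 and 28.4 kb in epithelium against 6.09 and 2.56 kb. No Hippo pathway gene was called (13 tested), and Zeb2 was the 1 call among 7 epithelial-mesenchymal transition regulators, longer in mesothelium (adjusted p = 0.011, 0.091 without epithelium replicate 1; 8.3e-05 to 0.214 over all alternatives). As lists, these pathways did not pass the camera test (adjusted p = 0.116 for Hedgehog, 0.127 for FGF, 0.571 for WNT, 0.911 for TGF-beta and BMP, 0.348 for retinoic acid, 0.744 for Notch, 0.510 for Hippo, 0.850 for epithelial-mesenchymal transition and 0.661 for basement membrane). Alternatives called the Hedgehog list (2 of 18, adjusted p = 0.036 to 0.535), the FGF list (1 of 18, 0.017 to 0.618) and the basement membrane list (2 of 19, 0.017 to 0.860). Adjusted over each list alone, 3 Hedgehog genes were longer in mesothelium and 1 in epithelium, 2 and 5 FGF genes, 3 and 1 WNT genes, 2 and 2 TGF-beta and BMP genes, 1 and 0 retinoic acid genes, 0 and 1 Notch genes, 0 and 0 Hippo genes, 1 and 2 transition regulators, and 3 and 4 basement membrane genes. The list mean and median differed in sign for TGF-beta and BMP (−0.03 and 0.07), Notch (−0.18 and 0.18) and the transition regulators (0.03 and −0.04).

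Markers of other cells that the gates could hold gave mixed values. Of 14 tested lung mesenchyme markers, Col3a1 and Tbx5 were longer in mesothelium (4 adjusted over the list alone), with a median log2 difference of 1.30 (camera adjusted p = 0.0031, adjusted p = 0.499 with an estimated correlation). The collagen gene Col1a1 had no peak in replicate 1 and 2.62 kb in replicate 2 of mesothelium, and no peak and 1.55 kb in epithelium. Of 7 tested endothelial markers, the receptor genes Tek and Kdr were longer in mesothelium, and the list did not pass (camera adjusted p = 0.166, 0.035 without mesothelium replicate 2 and 0.028 without epithelium replicate 2; 0.028 to 0.601 over all alternatives), although both gates excluded CD31. Tek lost its call without mesothelium replicate 2 (adjusted p = 0.179; 0.0017 to 0.659 over all alternatives), and Kdr without any of the 4 libraries (adjusted p = 0.127 to 0.258; 0.027 to 0.474 over all alternatives). Smooth muscle and pericyte markers (0 of 4 called, camera adjusted p = 0.315) and lymphatic endothelial markers (1 of 4, Reln, longer in epithelium, camera adjusted p = 0.503) did not pass. Reln lost its call without epithelium replicate 1 (adjusted p = 0.122) or replicate 2 (0.153; 0.0046 to 0.153 over all alternatives). The 2 tested neural crest and neuronal markers, Elavl4 and Erbb3, were not called singly (both adjusted over the list alone, longer in epithelium), with a list test near the threshold (camera adjusted p = 0.034, adjusted p = 0.447 with an estimated correlation and 0.051, 0.060 and 0.078 without mesothelium replicate 1, mesothelium replicate 2 and epithelium replicate 1; 0.035 to 0.502 over all alternatives). The 12 leukocyte markers were all below the length needed for a test, with at most 0.979 kb in any library, and fewer than 2 of 9 erythroid markers were long enough to test, so that list had no test. None of 12 tested housekeeping genes was called, although 11 of them had positive differences, with a median of 0.46 (camera adjusted p = 0.166).

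**Figure D3:**
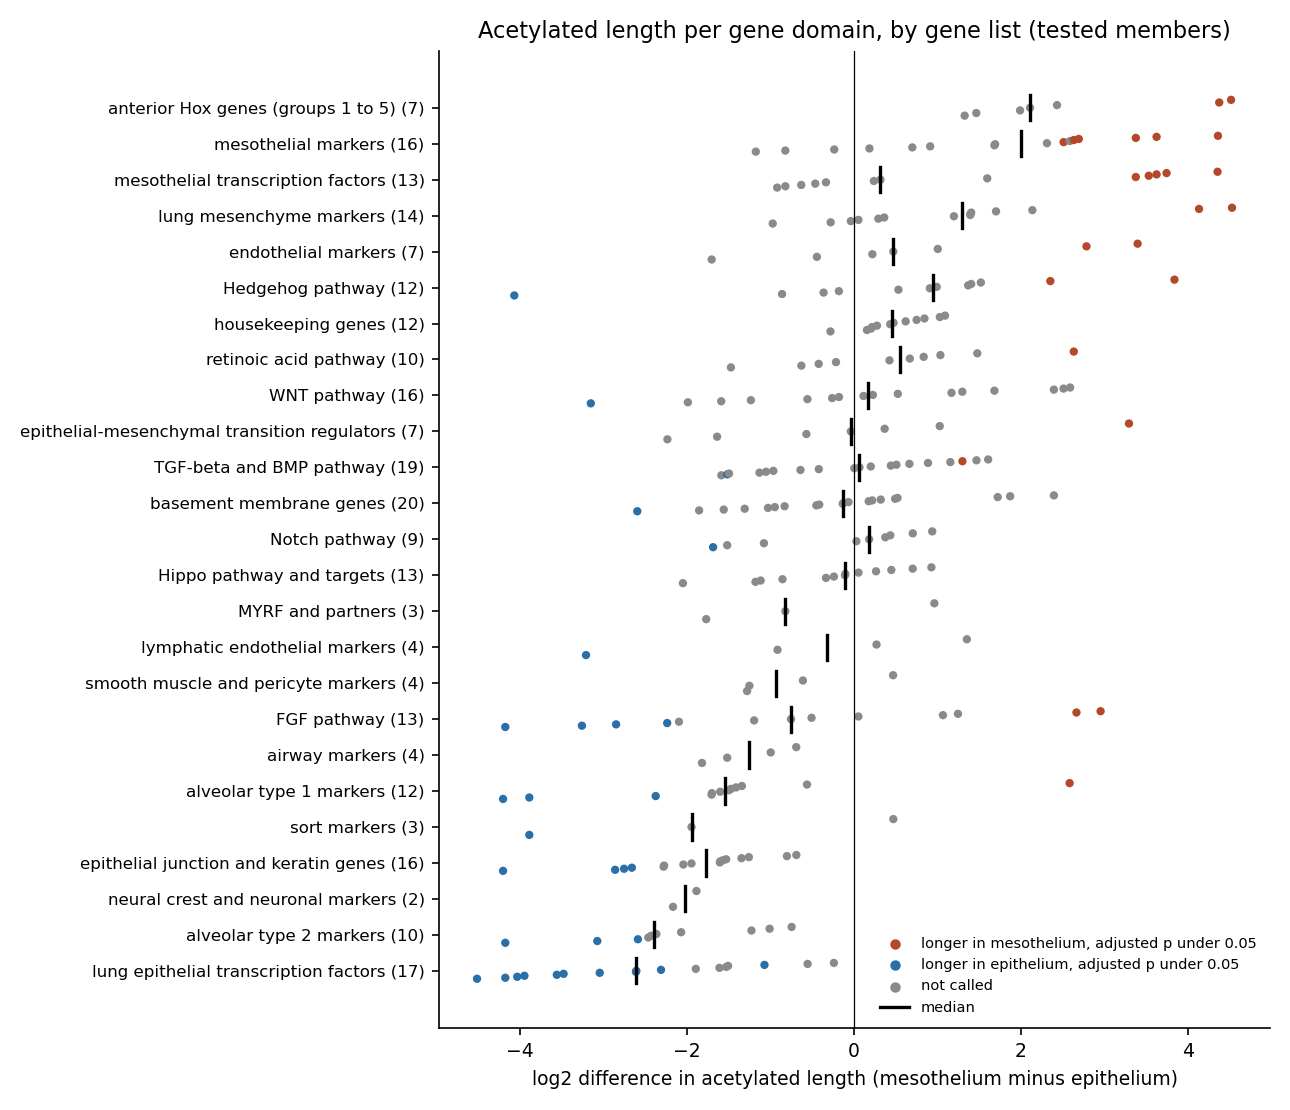
Log2 differences in acetylated length between mesothelium and epithelium (horizontal axis, positive where longer in mesothelium) for the tested members of each gene list (vertical axis, number tested in parentheses), 1 point per gene, coloured where called by limma, with the list median as a black bar. The median is 2.00 for mesothelial markers and −2.61 for lung epithelial transcription factors.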

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

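The thresholds of −log10 q of at least 2 and of 1 kb in width were chosen after seeing the data. The cause of the changes below was not tested, except where fewer peaks, domains or libraries entered by construction. Unknown depth and peaks near the caller's minimum limit all of these results. With a −log10 q of at least 4, the Jaccard difference, the lowest index within a cell type minus the highest between cell types, reversed (−0.00222 against 0.0303), 85 mesothelium-only and 10 epithelium-only regions and 93 and 4 genes with gene-end peaks were left, the distal odds ratios were 1.29 (p = 1.0) and 6.0 (p = 0.304, Fisher's exact test), 0 and 0 of 628 domains (23 at unadjusted p under 0.05 by limma) and 0 lists at gene ends for either cell type were called, 0 lists were longer in mesothelium and 1 in epithelium, and the mesothelial transcription factors (mean 0.553, adjusted p = 0.861; 7.4e-05 to 0.861 over all alternatives) lay below the other domains, whose median was 1.11. With a −log10 q of at least 2, the Jaccard difference was 0.0351, 1922 and 901 regions and 132 epithelium-only genes were left, 0 and 0 domains were called (960 at unadjusted p under 0.05) and 0 and 1 lists at gene ends. With peaks of at least 1 kb there were 1609 and 2028 regions, 287 epithelium-only genes, 0 and 0 called domains (1653 at unadjusted p under 0.05) and 4 lists longer in epithelium. A gene-end window of 2.5 kb gave 4 lists for mesothelium.

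Domains longer in mesothelium numbered 94 with gene bodies and 5 kb flanks, 89 unscaled, 88 scaled to total covered length (122 in epithelium), 94 after quantile normalization (125 in epithelium), 1 with 0.1 kb added (0 in epithelium) and 249 with 2 kb added. All 210 and 219 domains called after total scaling and quantile normalization were among the 413. Lists longer in epithelium numbered 4 with 5 kb flanks and 4 with 0.1 kb added, and with an estimated correlation 0 lists were called in mesothelium and 0 in epithelium. No scaling moved the median of all domains by over 0.1. Of the 50 named genes that were called, all kept their direction under each alternative in which they were tested, and 34 to 47 stayed called when 1 library was left out.

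Without 1 library, there were 4899 to 28906 mesothelium-only and 5930 to 35074 epithelium-only regions, 1308 to 1826 and 741 to 1242 genes with gene-end peaks, 1 to 3 and 2 to 5 lists at gene ends, 110 to 173 and 80 to 471 domains longer in mesothelium and epithelium, and 4 to 5 and 4 to 6 lists. The arm with 1 library was assumed to vary like the other, so leaving out a library can lower p-values and is not a stricter test. The replicate numbers did not pair the libraries (correlation of deviations 0.03). The replicate block called 210 and 348 domains, the 413 among them and all 50 called named genes.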

Other observations

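The tests against matched random lists, of adjacent pairs (except that of a divided region) and of the other splits of the libraries were chosen after the results were seen. The genes in this paragraph were chosen after their values were seen, and tests of them as groups, which would rest on the same calls, are not reported. Of 35 tested collagen genes, some of them in the fixed lists, 8 had longer domains in mesothelium, namely Col3a1, Col5a1, Col5a2, Col6a1, Col6a2, Col6a3, Col12a1 and Col14a1. Col18a1, a basement membrane collagen gene, was longer in epithelium. Col5a1 carried 12.2 and 9.49 kb in mesothelium against 1.23 and 1.44 kb in epithelium, and the collagen receptor gene Ddr2 carried 9.06 and 15.4 kb against 0.594 and 1.20 kb (adjusted p = 0.0029, limma). Zfpm2, which encodes a cofactor of GATA proteins, carried 21.8 and 36.6 kb against 3.05 and 2.70 kb (adjusted p = 0.00033), and Bnc2 carried 18.9 and 54.8 kb against 1.99 and 1.77 kb. All 4 tested Iroquois homeobox genes, Irx1, Irx2, Irx3 and Irx5, were longer in epithelium, and they form 2 adjacent pairs.

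Domains called in the same direction lay next to each other. Of the tested coding genes, 32 adjacent pairs were called in the same direction (8 in mesothelium, 24 in epithelium) and 5 in opposite directions. The 32 stood against a mean of 8.76 and a highest value of 22 in 10000 permutations (p = 0.0001, one-sided, the smallest they can give). Examples are Irx1 with Irx2, Irx3 with Irx5, Cdh3 with Cdh1, Mbip with Nkx2-1, Wdr11 with Fgfr2, Col3a1 with Col5a2 and Col6a2 with Col6a1. Single peaks divided between neighbouring domains do not make up all of these pairs, since 26 pairs had no peak that reached into both domains. The upper bound for the central 95% of permutations, which did not match genes on acetylated length, was 15. An acetylated region broken into several peaks can be divided between domains without such a peak, and the test cannot exclude it. Such a region, regulation shared by neighbouring genes, or an element assigned to the wrong neighbour may account for the rest, and the peak lists hold nothing that separates these.

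Mesothelium replicate 1, from 25k cells, carried more acetylated sequence at many epithelial genes than replicate 2, such as 5.85 against 0.417 kb at Foxa2, 8.05 against 1.03 kb at Cdh1 and 6.48 against 0.683 kb at Grhl2. Of 57 tested members of the 5 epithelial lists, 42 had a positive difference between these replicates after centring. Centring alone made this difference positive for Esrp1, Spint1, Sftpd, Lamp3 and Akap5, which had no peak in either replicate. The same holds for Gprc5a, with 0.988 against 0.993 kb. Epcam, the marker of the gate, had a negative difference with 0.685 against 1.02 kb. So did Cldn18 with 0.378 against 0.531 kb and Spint2 with 0.567 against 2.17 kb. Over 57 tested members of the 5 epithelial lists the median log2 difference between the replicates was 0.865. The upper bound for the central 95% of 10000 random lists matched on mean level was 0.308 (percentile 100.0). For the mesothelial markers the median was −0.869 (percentile 1.45), and for the same epithelial members between the epithelium replicates −0.097. The match used the mean over all 4 libraries, which at the epithelial lists came mostly from epithelium. The random lists were thus not matched on length in mesothelium, so these percentiles cannot weigh a difference between its replicates. Weaker enrichment of the library from fewer cells stays open. Centring each library on its median removes a general loss, and the genes compared are those that prompted the question. Some epithelial cells in the sort of mesothelium replicate 1, which the EPCAM gate should have removed, may also account for the difference. No biological explanation was tested, as both libraries belong to 1 group. Without this library, 471 domains were longer in epithelium and 173 in mesothelium.

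Of 14 tested lung mesenchyme markers, 2 were called and 11 had positive differences, with a median of 1.296 (percentile 100.0 of matched random lists; camera adjusted p = 0.499 with an estimated correlation), or 0.78 without Col3a1 and Tbx5. Mesenchymal cells may contribute, which the PDPN-positive, EPCAM-negative gate would remove only if they lacked PDPN, and 8 of the 20 listed genes are also in another list. Members of the list were uneven: Col3a1 was called (adjusted p = 0.00058, limma), and Col1a2, Col1a1, Pdgfrb and Lum were among the 12 that were not (adjusted p = 0.342, 0.894, 0.908 and 0.867). Smooth muscle and pericyte cells cannot be told apart from their absence with 4 tested genes (median −0.931, within the matched range from −1.10 to 1.17). Acetylation of these genes in mesothelial cells themselves stays open and was not tested.

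The 2 other splits of the 4 libraries into pairs called 0 domains (limma, 173 and 127 at unadjusted p under 0.05), against 413 for mesothelium against epithelium. Each of the other splits put a mesothelium and an epithelium library in each group. The difference between cell types thus added to their spread and lowered their calls by construction, so their counts give no support to the 413. Mesothelium against epithelium was 1 of 3 splits, too few for a share under 0.05.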
